A study of Mus musculus with 6 samples.

How the data were processed

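RNA was extracted from dissected olfactory epithelium of ED18.5 mouse embryos, per the labels' protocols. Equal amounts of RNA from 3 animals were pooled for each array, and labelled targets were made from 2.7 ug of total RNA and hybridised to exon arrays of the Mouse Exon 1.0 ST type, per the labels. The deposited values are on a log2 scale. The authors made them with RMA in Affymetrix Expression Console, per the submitters' processing notes, and RMA corrects background, normalizes quantiles between arrays and gives 1 value per probe set and array. The versions, the annotation level and the genome build are not given in the sources used here. Values ran from 1.51 to 14.05. Between-array normalization assumes that most probe sets do not change, and summarising a transcript over all its exon probes hides a change that is limited to some exons.

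The table held 23238 probe sets. Gene names came from the platform's annotation, which covered only identifiers in the numbering range of 16661 clusters. In that range 14945 clusters had 1 gene, 983 had several and 733 had none, and clusters with several genes or none were tested but not named. The other 6577 probe sets, none annotated, were left out and tested as an alternative. Of the single-gene clusters, 14884 matched a GRCm38.p6 gene table by Entrez identifier, and 0 symbols were changed. That table gave names, neighbours and the receptor class, read from family numbers among the synonyms, and none of its coordinates are given. A gene with several clusters was represented by the brightest.

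Differences (arrays labelled knockout minus wildtype) were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the 16661 clusters and a threshold of 0.05. Gene lists were tested with camera at its preset correlation of 0.01, adjusted over 29 lists, with camera at an estimated correlation and fry as checks. Means over lists per array were compared by an exact permutation test, whose smallest two-sided p with 3 and 3 arrays is 0.1, and by 95% intervals from the spread of the 3 and 3 arrays. Receptors within 1 Mb of the next formed a genomic cluster. Plots were drawn with matplotlib 3.10.9. The lists, tests and most alternatives were chosen before the data were examined. Camera was not run with robust estimation.

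The named genes follow a rule chosen with them. They are Emx2 and Emx1, the 8 odorant receptors with the largest called fall and the 8 with the largest called rise (7 passed), and the 12 genes outside the receptor families with the largest called fall and the 12 with the largest called rise. In each list they are up to 4 called members with the smallest p, or the 2 members with the smallest p, given as values, where none passed. Omp, Pde1c, Cngb1 and Slc24a4 were named after their values were seen.

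The steps were tested on simulated data with 16661 genes and 3 and 3 arrays, in which 200 genes changed. The fit recovered 52% of 1.5-fold changes, 90% of 2-fold, 98% of 4-fold and 100% of 8-fold changes, with 10 false calls. With no change simulated it made 0 calls and called 0 lists. The simulated genes varied independently, so this could not show false list calls that come from correlation between genes. The arrays correlated at 0.975 to 0.991 in pairs, and no pair shared more than 11 identical values, so each was counted as 1 replicate. Alternatives were other scalings, a filter on dim clusters, an intensity trend, robust estimation, array weights, the replicate number as a block, each array left out and other list tests. Chosen after seeing the data were the test of all probe sets, the Y-linked covariate, the subtraction of the marker mean, the left-out arrays for genes picked later and for the sustentacular comparison, and the genomic clusters with each array left out.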

Results

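RNA of the olfactory epithelium, the sensory sheet of the nose, was measured in mouse embryos at ED18.5, shortly before birth. Emx2 encodes a homeodomain transcription factor, and the comparison asks which transcripts of this tissue differ between wildtype embryos and embryos lacking Emx2. Each genotype had 3 arrays, and each array held a pool of RNA from 3 animals, so 9 animals stood behind each genotype. Values are log2 RMA signals from an Affymetrix exon array, 1 value per transcript cluster and array, and 16661 clusters were tested. The array medians lay between 7.64 and 7.73, and the number of arrays limits the precision.

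Emx2, the targeted gene, was at 8.44 ± 0.13 (SD, n = 3) in the wildtype arrays and at 8.37 ± 0.03 (SD, n = 3) in the arrays labelled knockout. The log2 difference was -0.07 with an SE of 0.09 (limma, adjusted p = 0.894), so the difference was smaller than the spread between the wildtype arrays. The cluster gives a single value over all its probes, and whether those probes lie outside the deleted part of the gene is not given in the sources used here, so this value checks nothing about the labels. Every direction given here therefore rests on the genotype labels alone, and the second group is called the arrays labelled knockout throughout. Emx1 was not analysed here.

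Across the 16661 clusters, 316 were lower and 24 were higher in the arrays labelled knockout (limma, adjusted p at or under 0.05), and 1689 had an unadjusted p under 0.05. Odorant receptors, the receptors by which olfactory neurons detect odorants, made up 187 of the lower and 7 of the higher clusters. Named genes outside the chemosensory receptor families gave 80 lower and 14 higher of 13999. Another 31 lower clusters and 1 higher cluster name several genes that include a chemosensory receptor. The count of lower clusters moved by over 1.5 times without wildtype replicate 1 (207), wildtype replicate 3 (185), knockout replicate 1 (145), knockout replicate 2 (182) or knockout replicate 3 (150), and the count of higher clusters did so without knockout replicate 2 (13) or knockout replicate 3 (14). It also moved to 109 of 12495 clusters above the 25th percentile of the mean, to 144 with all probe sets of the table tested and to 186 with Y-linked signal as a covariate.

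Odorant receptors were lower as a family. Of 709 receptor genes, 615 had a negative difference and 94 a positive one, and the median log2 difference was -0.66 with quartiles of -1.22 and -0.22, against -0.03 for all other clusters. Of these genes, 187 fell and 7 rose over all clusters tested, and 378 fell and 22 rose when adjusted over the list alone. At least 2-fold lower values were found for 249 receptors and at least 4-fold lower values for 59, while 8 were at least 2-fold higher. All 3 arrays of one genotype lay apart from the other 3 for 389 receptors in the lower and 23 in the higher direction, where chance gives 10% in both directions together for a single gene. The receptors were measured on the same 6 arrays, so they are not independent tests of that chance. The mean over all receptors was 5.26 ± 0.11 (SD, n = 3) in wildtype arrays and 4.49 ± 0.05 (SD, n = 3) in the arrays labelled knockout. Their difference was -0.77 (95% interval -0.97 to -0.58; two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays can give). The family's shift passed camera with its preset correlation (adjusted p = 6.45e-44), and adjusted p = 0.0258 with an estimated correlation.

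The sex of the embryos differed between pools. Y-linked Eif2s3y was between 7.78 and 8.89 in wildtype replicate 2 and knockout replicates 2 and 3, and between 3.30 and 3.69 in the other arrays. Among the arrays with low Y-linked signal, the receptor mean of knockout replicate 1 differed by -0.86 from the mean of wildtype replicates 1 and 3. Among those with high Y-linked signal, the mean of knockout replicates 2 and 3 differed by -0.67 from wildtype replicate 2. Markers of mesenchyme, cartilage and bone were higher in the same arrays in which the receptors were lower, with a median of 0.36.

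**Figure D1:**
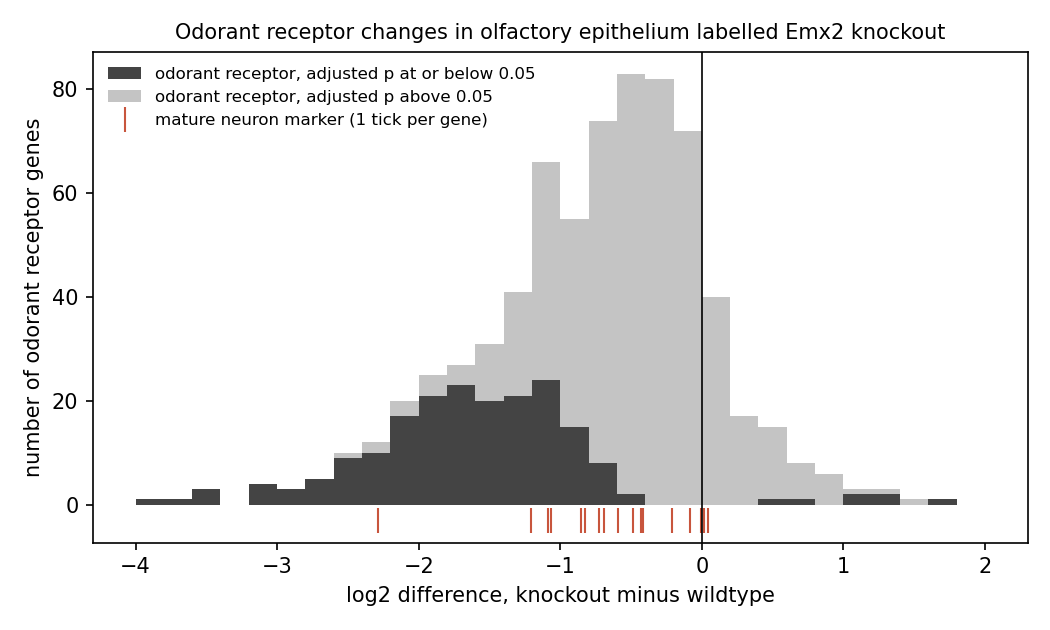
Histogram of the log2 difference (arrays labelled knockout minus wildtype, 3 arrays each) over 709 odorant receptor genes, with the number of genes on the vertical axis. Dark bars are the 187 receptors that fell and the 7 that rose at limma adjusted p at or under 0.05, and ticks below the axis mark the 17 mature neuron markers.

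The receptors with the largest measured log2 differences among those that fell were Olfr1208, at -3.95 (SE 0.22; limma adjusted p = 0.00111), and Olfr1110, at -3.71 (SE 0.09; limma adjusted p = 3.26e-05). They were followed by Olfr1325 at -3.57, Olfr263 at -3.54, Olfr726 at -3.51, Olfr820 at -3.04, Olfr130 at -3.03 and Olfr235 at -3.02. The arrays labelled knockout averaged 2.21 for Olfr263 to 4.66 for Olfr820 over these 8. The background of each cluster is not given in the sources used here, so how far it limits the sizes and the order of these falls is unknown. Olfr1184 at -1.91 and Olfr1123 at -1.59 had some of the smallest p-values. The 7 receptors that rose were Olfr15, from 9.60 to 11.24 (1.64, SE 0.21; limma adjusted p = 0.0145), Olfr736 at 1.37, Olfr464 at 1.25, Olfr303 at 1.19, Olfr698 at 1.05, Olfr1440 at 0.74 and Olfr370 at 0.52. Receptors of near-identical sequence can share probe signal, so single receptors are uncertain. With 1 array left out, limma's adjusted p passed 0.05 for Olfr820 in 4 of the 6 cases (highest 0.116, without wildtype replicate 3), Olfr15 in 3 (0.0594, without knockout replicate 1), Olfr303 in 1 (0.0524, without knockout replicate 1), Olfr1440 in 5 (0.0860, without knockout replicate 2) and Olfr370 in 6 (0.132, without knockout replicate 1).

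Receptors were also described by their mean level. The 237 dimmest had a median of -0.48, with 41 that fell. The middle 236 had a median of -0.96, with 76 that fell. The brightest 236 had a median of -0.59, with 70 that fell and all 7 that rose. Levels were means over all 6 arrays, which the change itself moves, so the placing of rises and falls by level is partly set by the split. The count of receptors that fell was 39 of the 144 receptors above the 25th percentile of all clusters and 101 with all probe sets of the table tested. It was 120 without wildtype replicate 3, 101 without knockout replicate 1, 112 without knockout replicate 2 and 108 without knockout replicate 3, and 4 receptors rose without knockout replicate 2 or knockout replicate 3.

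Receptors were then set against markers of mature olfactory neurons, the cells that carry them. The marker mean was 9.41 ± 0.20 (SD, n = 3) in wildtype arrays and 8.77 ± 0.14 (SD, n = 3) in the arrays labelled knockout, a difference of -0.64 (95% interval -1.03 to -0.25). The receptor mean minus the marker mean differed by -0.13 (95% interval -0.40 to 0.14; two-sided exact permutation p = 0.3), which is within the spread between arrays.

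Class I receptors, the family also found in fish, were compared with class II receptors. The median log2 difference was -0.82 over 92 class I receptors, of which 31 fell and 0 rose (limma), and -0.64 over 605 class II receptors, of which 155 fell and 7 rose. The class I mean minus the class II mean differed by -0.15 (95% interval -0.34 to 0.03; two-sided exact permutation p = 0.2), so a difference between the classes was not resolved. The value was -0.20, with an interval that excluded 0, without knockout replicate 1. It turned to 0.19 over the 17 class I and 125 class II receptors above the 25th percentile of all clusters, also with an interval that excluded 0, but that filter uses a mean over all 6 arrays which the change itself moves.

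Receptor genes lie in genomic clusters, and 26 clusters held at least 5 measured receptors, 666 receptors in all (order and neighbours from a GRCm38.p6 gene table, since no build is given for the array values). The median was negative in 25 of the 26 clusters. It was -1.68 in the 8 receptors from Olfr308 to Olfr292, -0.84 in the 134 receptors from Olfr992 to Olfr1271 and -0.09 in the 16 receptors from Olfr16 to Olfr414. Cluster membership held 7.39% of the variance of the differences, against a median of 3.66% over 10000 permutations of the cluster labels (permutation p = 0.0031). The permutation treats receptors as independent units, so its p measures spread among receptors and not between pools. Neighbouring receptors are often close in sequence and can share probe signal.

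Both other chemosensory families were lower on camera's preset test. Trace amine-associated receptors had a median of -0.65, and 2 of 8 fell, Taar4 by 1.36 and Taar2 by 0.74, with 3 lower when adjusted over the list alone. The median was -0.26 without knockout replicate 2. Camera gave this list adjusted p = 0.00937, and adjusted p = 0.172 with an estimated correlation. Vomeronasal receptors, which serve the detection of pheromones, had a median of -0.35, and 9 of 88 fell, with 20 lower when adjusted over the list alone. Among them were Vmn1r28 at -1.10, Vmn1r32 at -0.79, Vmn1r185 at -1.15 and Vmn1r85 at -0.99 (limma adjusted p from 0.00749 to 0.0252), all at low signal. In the same arrays the bone and cartilage markers had a median of 0.36. The list had camera adjusted p = 6.13e-12, and adjusted p = 0.140 with an estimated correlation. With 1 array left out, limma's adjusted p passed 0.05 for Taar2 in 4 of the 6 cases (highest 0.0629, without wildtype replicate 2), Taar4 in 5 (0.171, without knockout replicate 1), Vmn1r32 in 4 (0.0788) and Vmn1r185 in 2 (0.0863, both without knockout replicate 3) and Vmn1r85 in 5 (0.0892, without knockout replicate 1).

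Markers of mature olfactory neurons had a median log2 difference of -0.59 in 17 measured genes, 15 of them negative. S100a5, a calcium-binding protein of these neurons, fell by 2.29 (SE 0.27; limma adjusted p = 0.00983). Ano2, the chloride channel of olfactory transduction, fell by 1.21, Rtp2, which helps receptors reach the cell surface, by 1.09, and Umodl1 by 1.07. These 4 passed over all clusters and 11 were lower when adjusted over the list alone. Omp, the standard marker of mature neurons, was at -0.85 (limma adjusted p = 0.120), while Pde1c at -0.01, Cngb1 at 0.02 and Slc24a4 at 0.04 lay near 0. Camera gave the list adjusted p = 8.65e-09, and adjusted p = 0.413 with an estimated correlation. In the same arrays the bone and cartilage markers had a median of 0.36. With 1 array left out, limma's adjusted p passed 0.05 for Ano2 in 3 of the 6 cases (highest 0.0716) and Umodl1 in 5 (0.0788, both without knockout replicate 3) and Rtp2 in 4 (0.109, without knockout replicate 1).

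Markers of immature neurons had a smaller median of -0.30 in 11 genes. Gap43, a growth cone protein, fell by 0.52 and Trib3 by 0.83, and 9 were lower when adjusted over the list alone. For this list camera's adjusted p = 2.80e-06, and adjusted p = 0.115 with an estimated correlation. Among 10 globose basal and neuronal progenitor markers the median was -0.23 and Nhlh1, a transcription factor of new neurons, fell by 0.55, with 3 lower when adjusted over the list alone. On camera the list had adjusted p = 0.0352, and adjusted p = 0.608 with an estimated correlation. The bone and cartilage median of 0.36 stood beside these lists too. Without single arrays, limma's adjusted p passed 0.05 for Gap43 in 6 of the 6 cases (highest 0.163, without knockout replicate 1), Trib3 in 5 (0.173, without knockout replicate 3) and Nhlh1 in 6 (0.0976, without knockout replicate 1). Camera's adjusted p for the progenitor list was 0.118 without wildtype replicate 2, 0.0570 without knockout replicate 1 and 0.0847 without knockout replicate 3.

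Mesenchyme, cartilage and bone markers were all positive, 14 of 14, with a median of 0.36. Ibsp, a bone matrix protein, was at 1.04 and Sp7, a transcription factor of osteoblasts, at 0.59. No member passed over all clusters (limma; 7 had an unadjusted p under 0.05) and 2 were higher when adjusted over the list alone. The camera test gave adjusted p = 3.45e-11, and adjusted p = 0.0258 with an estimated correlation, so that only this list and the odorant receptors held on that test. Ibsp passed limma's threshold without wildtype replicate 2 (adjusted p = 0.0299).

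Sustentacular cells, the supporting cells of the epithelium, had a marker median of 0.17 in 9 genes, with Muc2 at 0.50 and Cyp1a2 at 0.74. None passed over all clusters or adjusted over the list alone (limma; 2 had an unadjusted p under 0.05). Camera gave adjusted p = 0.00333, and adjusted p = 0.152 with an estimated correlation. The median was 0.08 without wildtype replicate 1 and 0.10 without wildtype replicate 2 or knockout replicate 2. Muc2 passed limma's threshold without wildtype replicate 1 (adjusted p = 0.0467). Skeletal muscle markers had a median of 0.50 in 6 genes, all positive, with Ckm at 0.53 and Tnnt3 at 0.57, and none passed over all clusters, adjusted over the list alone or at an unadjusted p under 0.05 (limma). Camera gave adjusted p = 0.00527, and adjusted p = 0.666 with an estimated correlation. Camera's adjusted p was 0.0979 without wildtype replicate 1 (median 0.30), 0.0863 without knockout replicate 2 (median 0.22) and 0.0785 without knockout replicate 3, and the median was 0.82 without knockout replicate 1.

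**Figure D2:**
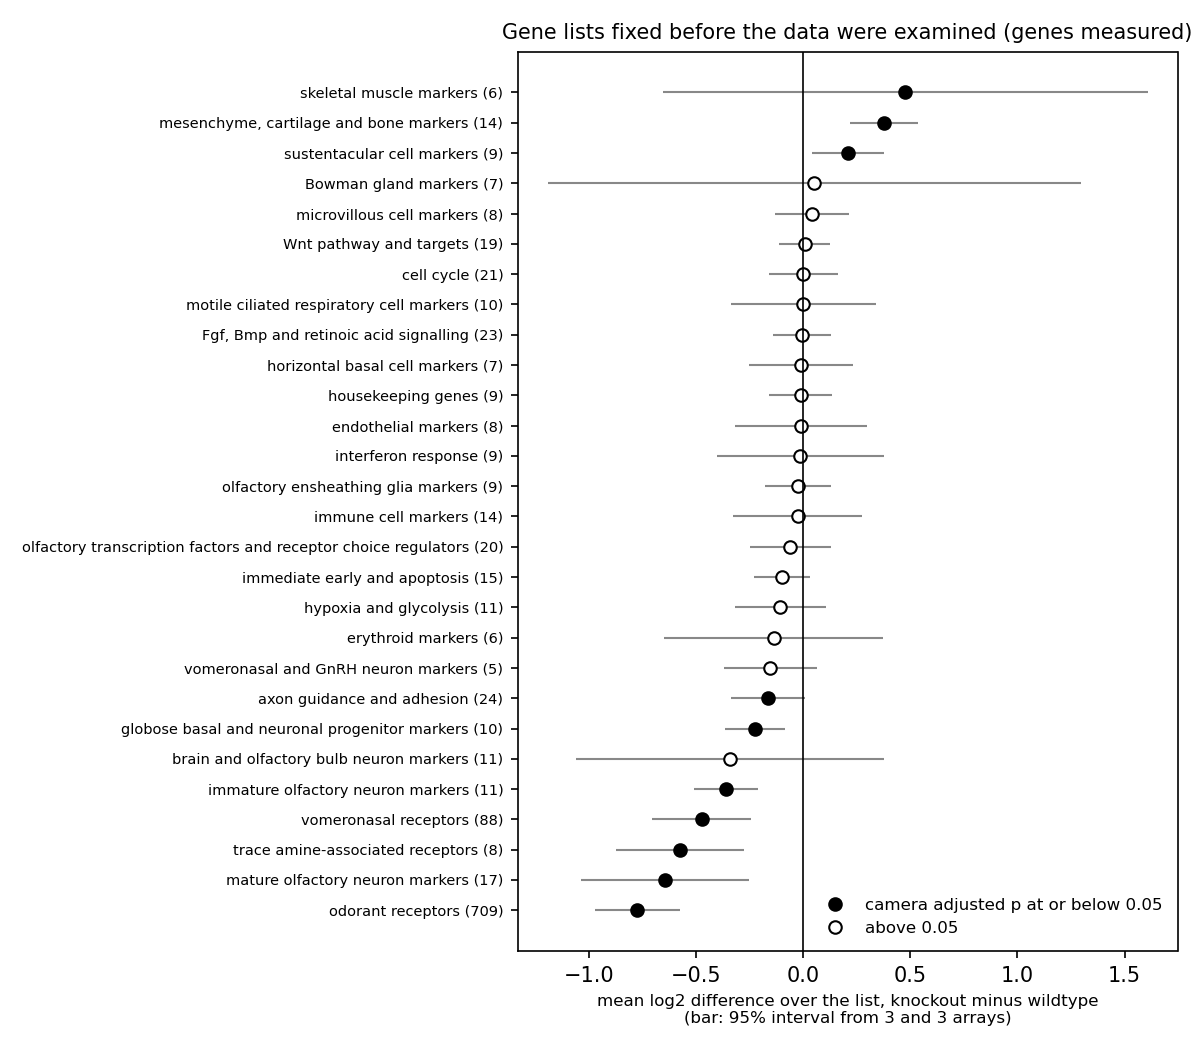
Mean log2 difference of 28 of the 29 gene lists (arrays labelled knockout minus wildtype), the sex-linked list left out, with 95% intervals from 3 and 3 arrays and the number of measured genes in parentheses. Filled points passed camera with its preset correlation; odorant receptors lie lowest at -0.77 and mesenchyme, cartilage and bone markers lie at 0.38.

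Of the genes of axon guidance and adhesion, 2 of 24 fell. Cntn4, an adhesion protein of axons, fell by 1.06 (SE 0.09; limma adjusted p = 0.00472), and Slit1, a repellent guidance cue, by 0.56 (limma adjusted p = 0.0495). The list had a median of -0.14, with 5 lower when adjusted over the list alone. In those arrays the bone and cartilage median was 0.36. Camera gave adjusted p = 0.0456, and adjusted p = 0.766 with an estimated correlation. Camera's adjusted p was 0.355 without wildtype replicate 2 (median -0.05), 0.159 without wildtype replicate 1, 0.185 without knockout replicate 2 and 0.0956 without knockout replicate 3, and limma's for Slit1 passed 0.05 in 5 of the 6 cases (highest 0.186, without knockout replicate 3).

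Outside the receptor families the largest falls after S100a5 were those of Nqo1, a quinone reductase of dorsal-zone olfactory neurons, at -1.58 (SE 0.23; limma adjusted p = 0.0214), and Rims3, a protein of the presynaptic active zone, at -1.45 (SE 0.12; limma adjusted p = 0.00460). Further proteins of vesicles and secretion were Rab3c at -1.41, the prohormone convertase Pcsk1 at -1.25 and the granin Chga at -1.16. Clgn was at -1.41, Cidea at -1.20, Gng3 at -1.15, Vsnl1 at -1.15 and the potassium channel Kcnc4 at -1.13. The bone and cartilage median of 0.36 stood beside these falls. With 1 array left out, limma's adjusted p passed 0.05 for Nqo1 in 4 of the 6 cases (highest 0.0915) and Gng3 in 3 (0.0840, both without knockout replicate 1), Rab3c in 5 (0.0927, without wildtype replicate 3) and Pcsk1 in 3 (0.0788, without knockout replicate 3).

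Lmo3, a LIM-only transcriptional cofactor, rose most, from 6.78 to 8.70 (1.91, SE 0.11; limma adjusted p = 0.00116). The collagenase Mmp13 rose by 1.31 and Panx3, a channel protein of cartilage and bone, by 0.75, beside the higher bone and cartilage list. Several channels and signalling proteins rose, namely Trpa1 by 1.25, Trpc4 by 1.01, Kcnh1 by 1.00, Rgs7 by 1.00, the receptor kinase Alk by 0.92 and Rapgef5 by 0.63. Prmt8 rose by 0.83. E330013P04Rik, the measured gene next to Emx2 in the GRCm38.p6 gene table, rose by 1.30 (SE 0.10; limma adjusted p = 0.00292). Gad2, which makes the transmitter GABA, rose by 0.98, while the other 10 of the 11 brain and olfactory bulb neuron markers were negative (list median -0.38, camera adjusted p = 0.358; 1 higher when adjusted over the list alone). With 1 array left out, limma's adjusted p passed 0.05 for Trpc4 in 3 of the 6 cases (highest 0.0633), Gad2 in 5 (0.0888) and Rapgef5 in 6 (0.172, all without knockout replicate 1) and Panx3 in 4 (0.0588, without knockout replicate 3), and camera called the brain list without wildtype replicate 1 (adjusted p = 0.00992). In all 54 named genes that passed, the 3 arrays of one genotype lay apart from the other 3. Since these genes were picked by that difference, this separation is no further support. With each array left out in turn, 29 of the 54 passed every time.

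**Figure D3:**
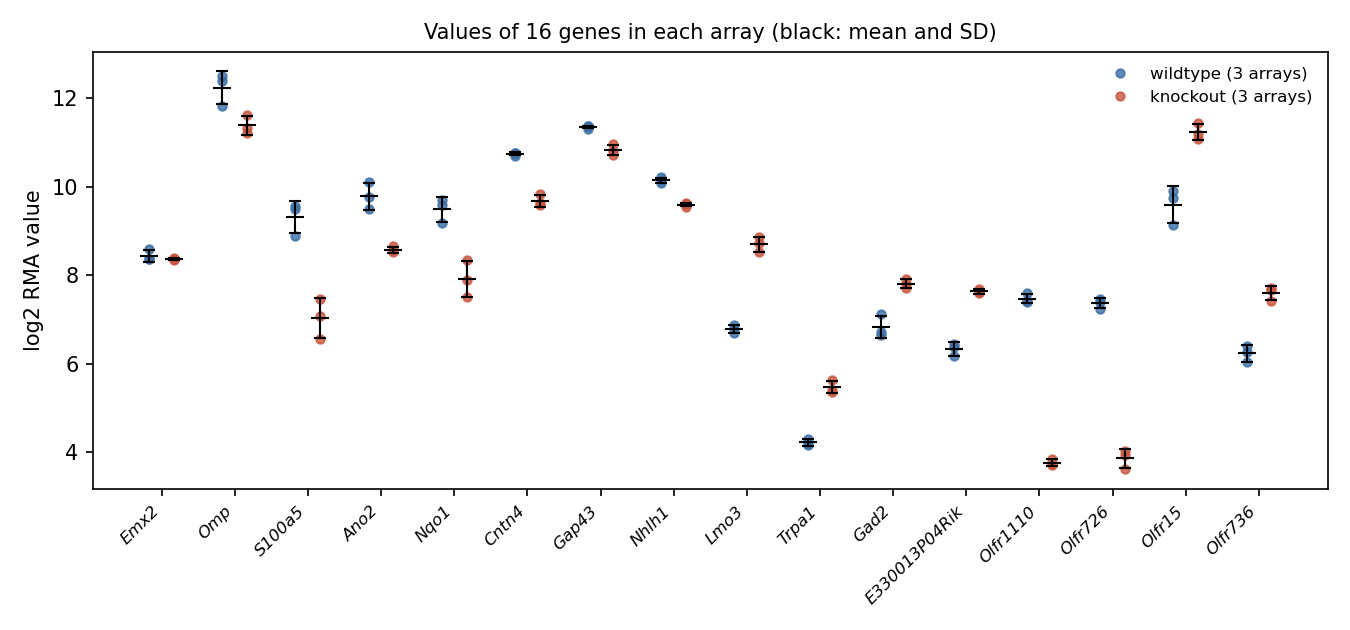
Log2 RMA values of 16 genes in each of the 3 wildtype arrays and the 3 arrays labelled knockout, with black marks for the mean and SD. Emx2 overlaps between the groups, at 8.44 and 8.37, while Olfr1110 and Olfr726 are lower and Lmo3 and Olfr15 higher in the arrays labelled knockout.

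The remaining 18 lists, with 203 measured members, held no member past limma's adjusted p of 0.05 over all clusters and were not called by camera (adjusted p from 0.312 to 0.840), and 9 members had an unadjusted p under 0.05. Of these lists, 1 member of the vomeronasal and GnRH neuron markers was lower when adjusted over the list alone. Cell cycle genes had a median of 0.01 in 21 genes, with Ccna2 at 0.19 and Mcm7 at -0.25. Olfactory transcription factors and regulators of receptor choice had a median of -0.03 in 20 genes, with Ebf4 at -0.35 and Atf5 at -0.37. Medians of the other cell types were -0.04 for horizontal basal cells (Krt15 -0.23, Cd44 0.18), 0.12 for Bowman glands (Gpx6 -0.78, Sox9 0.14) and 0.02 for microvillous cells (Cftr 0.20, Chat 0.05). They were -0.10 for vomeronasal and GnRH neurons (Tfap2e -0.51, Gnao1 -0.28), 0.05 for olfactory ensheathing glia (Mbp 0.24, Fabp7 -0.45) and -0.05 for ciliated respiratory cells (Dnah5 0.30, Hydin 0.23). Erythroid markers were at -0.12 (Car2 -0.23, Hba-x -0.17), immune markers at -0.03 (Ngp -0.40, Cd68 0.31) and endothelial markers at -0.01 (Esam -0.15, Cdh5 0.11). Among pathways the medians were 0.01 for Wnt (Wif1 0.41, Wnt4 -0.12), 0.00 for Fgf, Bmp and retinoic acid (Fgf9 -0.27, Fgfr2 0.24) and -0.06 for immediate early and apoptosis genes (Cdkn1a -0.60, Ddit3 -0.68). They were -0.18 for hypoxia and glycolysis (Ndrg1 -0.41, Slc2a3 -0.33), -0.02 for interferon response (Mx1 0.23, Bst2 -0.22) and -0.01 for housekeeping genes (Sdha -0.11, Tfrc 0.10). The sex-linked list, Eif2s3y at 1.53 and Kdm5d at 0.97, followed the pools' sex. The median, the mean and the camera direction differed in sign for the lists of horizontal basal, ensheathing glia, ciliated, immune, endothelial, Fgf, interferon and housekeeping genes. Camera called the Bowman gland list without wildtype replicate 1 (adjusted p = 0.00894) and the sex-linked list without wildtype replicate 2 (0.0453) or knockout replicate 1 (0.0151).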

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

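Of the tests in this part, the comparison with sustentacular markers, the counts of receptors and markers relative to the marker mean and the Omp version were chosen after the result was seen, and the test with the Y-linked covariate and the sustentacular comparison with arrays left out were added alternatives.

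Probe sets outside the annotated numbering range were not used in the comparisons. With all probe sets tested together, 4 of these 6577 passed limma's adjusted p of 0.05, 1 lower and 3 higher. In a fit of their own 0 passed, and 356 (5.41%) had an unadjusted p under 0.05. They carry no gene name here.

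The receptor family was lower in the arrays labelled knockout. The tables argue against an array-wide scaling difference as the whole cause. After quantile normalization again the median receptor change relative to other clusters was -0.54 (common-median scalings move all clusters of an array alike and test nothing here). Most other clusters were brighter than the receptors, so a difference limited to low signal was not tested. The median was -0.37 over the 144 receptors above the 25th percentile of all clusters. The sex of the pooled embryos is argued against too, since the median was -0.66 with Y-linked signal as a covariate. Provided sustentacular markers are confined to the epithelium, which was not tested, more tissue from outside it would lower them with the neuron markers. The sustentacular mean minus the mature marker mean differed by 0.85 (95% interval 0.53 to 1.18). It was 0.77 to 0.95 with 1 array left out, each interval above 0. Under that condition this argues against such tissue as the whole cause. More such tissue stays open as part of the cause, since bone and cartilage markers (14 of 14, median 0.36; camera adjusted p = 0.0258 with an estimated correlation) and skeletal muscle markers (6 of 6, median 0.50; adjusted p = 0.666) were positive. Fewer mature neurons may account for the mean fall, since receptor mean minus marker mean was -0.13 with a 95% interval of -0.40 to 0.14. That interval also allows a larger fall of the receptors than of the markers. The receptors were dimmer than the markers (wildtype means 5.26 and 9.41), and how far background limits their fall is unknown. Lower transcription per neuron stays open beside fewer mature neurons.

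Whether the receptors that fell did so by the marker amount was left open. With each array's marker mean subtracted, 207 receptors were lower and 155 higher when adjusted over the list alone (at most 5 lower in any other split of the arrays), and 116 were lower with Omp alone subtracted. On the same test 2 of the 17 markers were themselves lower than the marker mean and 4 higher. Before the subtraction the markers ran from S100a5 at -2.29 to Slc24a4 at 0.04. Receptors lower than that mean therefore decide nothing about a uniform loss of mature neurons. A uniform loss alone would raise no receptor. Yet 7 receptors rose over all clusters (limma; 4 to 7 with 1 array left out) and 22 when adjusted over the list alone. For the receptors that rose, this argues against a uniform loss as the only cause. This use of the counts was chosen after they were seen, and shared probe signal leaves single receptors uncertain.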

How the results depend on the processing

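The added tests here, chosen after seeing the data, are all probe sets, the Y-linked covariate, marker subtraction and the clusters with arrays left out. The 340 called clusters kept their direction under each scaling, variance model, block, covariate and left-out array. Under the 25th percentile filter, 148 of 148 measured did so. Direction was not counted for the marker subtraction. The intensity trend, robust estimation and the block leave the fitted difference as it is. The clusters were also picked by their calls in these data, so kept directions are little support. The receptor shift and Emx2 stayed on their side of the threshold wherever they were computed, and the genomic clusters did so at both other distances and with each array left out, the only settings run for them. The receptor shift ran from -0.78 to -0.37, with camera adjusted p from 5.77e-54 to 0.0258. Receptor minus marker mean ran from -0.20 to 0.10, its interval including 0 each time.

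The filter on dim clusters gave 109 lower clusters and 39 lower receptors, with fewer tested, and turned class I against class II to 0.19; the cause was not tested. All probe sets gave 144 lower clusters and 101 lower receptors. The covariate gave 186 lower clusters. Marker subtraction gave 167 higher receptors (218 lower). Of 10 lists called, 2 held with an estimated correlation and 6 with fry. With 1 array left out, lower clusters numbered 145 to 224, higher ones 13 to 23, lower receptors 101 to 154 and higher ones 4 to 7, with fewer samples behind each, and class I against class II ran from -0.20 to -0.11.

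Same-numbered arrays did not deviate together (correlations 0.01, 0.05 and -0.17), so these values gave no sign that the numbers pair the samples. With so few arrays they cannot exclude a pairing. The replicate block gave 168 lower clusters, and 168 of its 184 calls were also called without it. Not every array correlated best with its own number.

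The 10 splits of the 6 arrays are too few for a share under 0.05, and 1 of 10, the real one, was as large in each case. It gave 340 clusters (highest other 2), 194 receptors (0) and a median receptor difference of 0.66 in size (0.32). Each other split mixes both genotypes, so a difference between them adds to its spread and lowers its values. The low values there are therefore no measure of chance alone. At an unadjusted p under 0.05 another split, wildtype replicate 1 with knockout replicates 1 and 3, gave 1792 clusters against 1689, with 0 called. Signal over background per cluster was not measured, so its limit on falls of dim receptors is unknown.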

Other observations

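Several genes of neuronal excitability and secretion outside the fixed lists were also lower in the arrays labelled knockout; they were picked after their values were seen. The synaptic vesicle proteins Syt1 and Syp were at -0.88 and -0.69, Syt4 was at -0.62 and the granin Chgb at -0.57 (limma adjusted p from 0.0169 to 0.0480). The dopamine receptor Drd2 was at -0.71 (limma adjusted p = 0.0415) and the pacemaker channel Hcn2 at -0.54 (0.0230). When single arrays were left out, Syt4, Chgb and Hcn2 lost the call in 6 of 6 cases, Syp and Drd2 in 5 and Syt1 in 3. The highest adjusted p was 0.183 for Syt4 and 0.0747 for Syt1 without knockout replicate 3, and 0.111 for Syp, 0.120 for Chgb, 0.164 for Drd2 and 0.102 for Hcn2 without knockout replicate 1. These are single genes, no enrichment was tested, and the bone and cartilage median of 0.36 stood beside these falls.

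Of the tests in this part, those on Emx2 probes and on the single genes with arrays left out were chosen after the result was seen. The comparison of receptor classes was planned, but its use for Nqo1 was chosen after the result was seen. The second window shape for the neighbours of Emx2 was chosen after the first had been run.

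Emx2 was not lower in the arrays labelled knockout. The receptor means left a gap of 0.64 between the groups against a largest range of 0.22 within a group. Provided receptor level follows genotype, which rests on these same labels, this argues against a wrong label on single arrays. Over all clusters the groups were less distinct. Wildtype replicate 1 correlated at 0.98389 with knockout replicate 3 and at 0.98376 with wildtype replicate 3. An exchange of both whole groups was not excluded. Probes outside the deleted part could give the same value, and since the table holds 1 Emx2 cluster with a single value over its probes, this cannot be told apart from an unchanged transcript. Of the 60 nearest measured genes (50 on one side and 10 on the other), 8 or 13.3% had an unadjusted p under 0.05, and E330013P04Rik alone passed adjustment. Windows of 50 genes on each side, run first, had a 95th percentile of 21% elsewhere, or 11% without chemosensory receptors. Windows of the same 50 and 10 had 25%, or 13.3% without receptors. Of the nearest 10 genes on each side, 3 or 15% had such a p, against a 95th percentile of 30%, or 20% without receptors. The share lay above the 95th percentile only against receptor-free windows of 50 on each side, which hold more than the 60 genes at Emx2. Whether DNA of the targeted strain kept around Emx2 may account for these genes thus depends on the window and stays open.

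Nqo1, a gene of dorsal-zone neurons, fell by 1.58. A larger loss of dorsal neurons would lower class I receptors, which those neurons use, more than class II. The class I mean minus the class II mean was -0.15 (95% interval -0.34 to 0.03), which neither shows nor excludes it. The value was -0.20 without knockout replicate 1, with an interval that excluded 0. It was 0.19 among the 17 class I and 125 class II receptors left by the filter on dim clusters, which is set by a mean that the change itself moves and decides nothing, so the question stays open.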
